A study of Mus musculus with 18 samples.

How the data were processed

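Microglia were isolated from the brains of untreated C57Bl/6 mice by a Percoll gradient and sorted as cells positive for CD45 and CD11b and negative for Gr1, per the labels' protocols. The total RNA was amplified with the Ovation PicoSL WTA System V2, biotin-labelled with the Encore Biotin Module and hybridised to Affymetrix gene arrays. The 18 arrays fall into 6 groups of 3 by the region and age in the labels: cortex and corpus callosum, each at postnatal day 3 (P3), at postnatal day 7 (P7) and in the adult. The labels do not say how many animals contributed to an array, whether cells of several animals were pooled, or which sex the animals were. The p-values therefore measure only the spread between these samples, and 3 arrays per group limit the precision of every value.

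The values are the log2 expression levels deposited by the authors, 1 per probe set and array. They had been made with the robust multi-array average (RMA), per the submitters' processing notes, which subtracts background, makes the distributions of the arrays alike and combines the probes of a probe set. The version and settings of RMA and the array annotation build are not given in the sources used here. The base of the logarithm is not stated either and was taken as 2, the usual output of RMA, because the values ran from 0.87 to 13.8. The medians of the arrays lay between 5.58 and 5.74. A change of total RNA per cell cannot be seen after RMA, and the combination over probes compresses large differences. Signal was not told apart from background, so the size of a difference from a level below the medians, as for Atp6v0d2 and H1f5, is uncertain. On a P7 or adult array, 6.35% of P3 values recurred with the same digits, against 6.00% of P7 and adult values. As no arrays known to be normalized apart were compared, joint normalization stays open. The labels of the P3 arrays carry another prefix than those of the P7 and adult arrays. Age and array set therefore coincide in any comparison of P3 with P7, whereas each comparison of the regions at a given age, and of adult with P7, lies within a single array set. A comparison of regional differences between ages cancels a set effect that is equal in both regions.

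The file held 41345 probe sets. In GEO's platform annotation 23521 of them had 1 gene symbol, 1814 had several and 16010 had none. Identifiers of 23328 probe sets were matched to the RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names only, and 0 symbols needed an update. A gene was represented by its probe set with the highest mean over all arrays, which concerned 1082 symbols with more than 1 probe set, and 22180 genes were tested. Probe sets with several symbols or none were tested apart and not named. All arrays were used.

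All 18 arrays entered a single linear model with a mean for each group in limma 3.58.1 (R 4.3.3), fitted with lmFit, contrasts.fit and eBayes without trend, with 12 residual degrees of freedom. The 10 comparisons were corpus callosum against cortex at each age, adult against P7 and P7 against P3 in each region, and the differences of the regional difference between each pair of ages. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Unless stated otherwise, each adjusted p of a gene comes from limma, the value after ± is a standard error where it follows a difference and a standard deviation where it follows a level, and n is 3 arrays per group. Complete separation of 3 arrays from 3 others arises by chance in 10% of genes, and the smallest two-sided permutation p for such groups is 0.1, so no exact test of a gene could pass.

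Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 26 lists of a comparison. The lists comprised 16 groups of microglial and metabolic genes and 10 groups of markers of other cells. Because a preset correlation gives small p-values for co-regulated genes, camera was repeated with the correlation estimated from the arrays, and fry was run as well; fry asks whether the genes of a list move on balance in a single direction and does not compare them with other genes. Some listed genes were not used here, among them 7 of the 10 erythroid genes. There were 25 genes that sat in 2 lists, Igf1, Csf1, Fabp5 and Lpl among them. Xist, Kdm5d, Eif2s3y and Uty served to describe the sex of the animals and were not tested as a list.

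The comparisons, the lists, the tests and most alternatives were chosen before the data were examined. So was the rule for the genes named: in each comparison up to 8 called genes per direction with the largest difference whose arrays were completely separated between the groups (a condition dropped for differences between ages of the regional difference), without genes known only by a clone, locus or small RNA name; up to 3 called members per direction of each list; a fixed panel of Igf1, Itgax, Clec7a, P2ry12, Tmem119 and Mki67; and, where fewer than 5 genes passed, the 5 genes with the smallest p. The number was capped at 30 per comparison. List members named beyond this cap for adult against P7 were picked by the same rule per list, an extension made after the values were seen. A second probe set of the same gene disagreed in some cases. Taf1d was called with its brightest probe set only, Fabp5 at P3 had an adjusted p of 0.0515 with a second probe set and, for adult against P7 in cortex, 0.0691 with another, Pgam1 at P7 had 0.909 with its other probe set and 0.988 for the regional difference between P7 and adult, and Lpl had 0.237 for that between P3 and adult. With another probe set Selplg, Cd24a and Syt4 in cortex between P3 and P7 had 0.0672, 0.161 and 0.138, and Slc36a4, Cd24a and Erdr1 in corpus callosum between P3 and P7 had 0.357, 0.148 and 0.142 with theirs.

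The alternatives were: leaving out each array in turn, leaving out dim probe sets, quantile normalization applied again, centring each array on its median, eBayes with trend and robust estimation, a fit on the compared groups alone, array weights, all probe sets with 1 symbol, an absolute log2 difference of at least 1, and the replicate number as a block. Added after the data were seen were the omission of both adult replicate 1 arrays, the mean of the neuron markers as a covariate, and the difference of Xist and the Y-linked transcripts as a covariate. Leaving out an array leaves groups of 2 arrays that borrow their spread from the other groups. A count was taken as moved where it changed by more than 1.5 times.

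The pipeline was tested on simulated data in which 200 of 22180 genes were changed by known amounts (seed 1). For corpus callosum against cortex at P7 it recovered 22%, 84% and 100% of the genes changed by 0.5, 1 and 2 log2 units. At P3 these shares were 18%, 70% and 98%, and in the adult 18%, 78% and 96%. For adult against P7 they were 18%, 74% and 100% in cortex and 18%, 86% and 100% in corpus callosum, and for P7 against P3 they were 34%, 82% and 98% in cortex and 18%, 86% and 98% in corpus callosum. The differences of the regional difference were found less readily: 0%, 44% and 96% between P3 and P7, 0%, 54% and 94% between P7 and adult, and 2%, 66% and 100% between P3 and adult. Each comparison had 4 to 11 false calls and 0 wrong signs. The real spread may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.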

Results

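Microglia, the resident macrophages of the brain, were sorted from cortex and from corpus callosum of healthy C57Bl/6 mice at postnatal day 3 (P3), at postnatal day 7 (P7) and in adulthood. Their RNA was measured on expression arrays. The corpus callosum is a white matter tract whose axons become myelinated after birth. The title of the series concerns the part that microglia play in myelin formation and in the upkeep of oligodendrocytes. Each of the 6 groups held 3 arrays, and 22180 genes were compared across all 18. The first principal component took up 39.5% of the variance and set the adult arrays apart from the P3 and P7 arrays. Microglial identity transcripts were abundant at every age: P2ry12, a purinergic receptor typical of microglia, had group means between 11.60 and 12.21 log2 units. Both adult replicate 1 arrays stood somewhat apart, with a mean correlation to all other arrays of 0.938 in cortex and 0.934 in corpus callosum, against 0.944 or more for every other array. Xist, which is transcribed in females, and the Y-linked Kdm5d varied within every group. In cortex at P7, for example, replicate 1 had 11.84 for Xist and 4.09 for Kdm5d, and replicate 2 had 4.07 and 7.61. Both were high on corpus callosum replicate 1 at P7 (10.91 and 6.64) and, at P3, on corpus callosum replicate 3 (10.45 and 7.28) and cortex replicates 2 (9.52 and 7.01) and 3 (8.08 and 7.52).

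**Figure D1:**
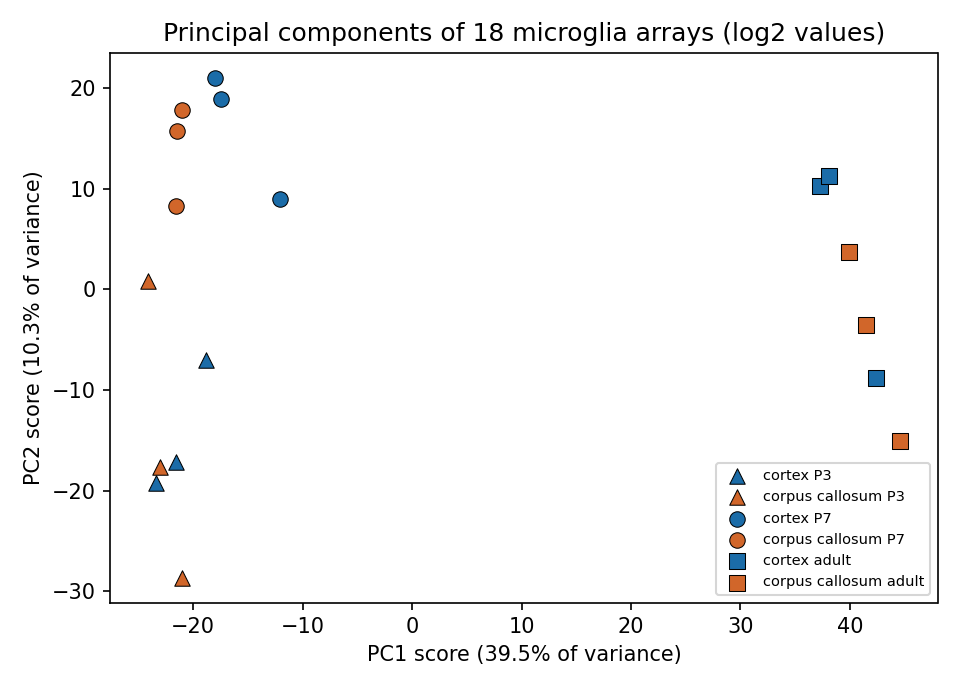
Principal component scores of the 18 arrays from their log2 values, with PC1 (39.5% of the variance) on the horizontal and PC2 (10.3%) on the vertical axis; each symbol is an array, its colour the region and its shape the age. The adult arrays lie at PC1 scores of 37.3 to 44.6 and all P3 and P7 arrays at -24.1 to -12.1.

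The comparison of corpus callosum with cortex at P7 asks which transcripts mark white matter microglia while myelin is being formed. Atp6v0d2, a subunit of the vacuolar proton pump, was higher in corpus callosum microglia (4.40 ± 0.46 log2 units, adjusted p 5.31e-05), at 8.95 ± 0.64 against 4.55 ± 0.62 in cortex, a level below the medians of all arrays. Gpnmb, a transmembrane glycoprotein of phagocytes, was 9.42-fold higher (3.24 ± 0.34, adjusted p 5.31e-05). Itgax, which encodes CD11c, was 8.61-fold higher (3.11 ± 0.28, adjusted p 1.17e-05). Igf1, a growth factor that acts on oligodendrocytes and neurons, was 5.41-fold higher (2.44 ± 0.27, adjusted p 9.05e-05), with 7.40 ± 0.58 in cortex and 9.84 ± 0.56 in corpus callosum. Clec7a, the beta-glucan receptor dectin-1, was 7.13-fold higher (2.83 ± 0.33, adjusted p 0.000145), and Hpse, which encodes heparanase, 6.31-fold higher (2.66 ± 0.20, adjusted p 2.19e-06). The cytokine gene Tnfsf18 (3.11 ± 0.49, adjusted p 0.00331) and the CD200 receptor family gene Cd200r4 (2.54 ± 0.31, adjusted p 0.000266) complete the 8 largest differences. In all, 100 genes differed, 99 of them higher in corpus callosum. The exception was Zfp975 (-0.70 ± 0.14, adjusted p 0.0271). All 100 had completely separated arrays, as did 16.7% of all genes, where chance gives 10%.

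By gene group, the axon tract and CD11c-type list, made up of genes of microglia found along developing axon tracts, rose with 14 of 23 measured members higher (20 higher and 1 lower when adjusted over the list alone). It had a median of 0.84 and an adjusted p of 1.28e-51 (adjusted p = 0.000363 with an estimated correlation). Fabp5, a fatty acid carrier (2.04 ± 0.26, adjusted p 0.00045), and Csf1, the ligand of the microglial survival receptor (1.97 ± 0.28, adjusted p 0.00118), were among its members. In the lipid handling list 7 of 15 members rose (10 over the list alone). Among them were the apolipoprotein gene Apoc1 (2.19 ± 0.25, adjusted p 0.000107) and Plin2, which coats lipid droplets (1.09 ± 0.19, adjusted p 0.00875). The list had a median of 0.68 and an adjusted p of 9.19e-19 (adjusted p = 0.00183 with an estimated correlation). Of the glycolytic enzymes Tpi1 (1.17 ± 0.20, adjusted p 0.00733), Pgk1 (0.93 ± 0.17, adjusted p 0.0109) and Pgam1 (0.82 ± 0.15, adjusted p 0.0115) rose, 3 of 13 members (10 over the list alone). The list had a median of 0.71 and an adjusted p of 8.05e-14 (adjusted p = 0.0459 with an estimated correlation). The lysosome list had 2 of 23 members higher (6 over the list alone), Lipa, the acid lipase (0.84 ± 0.15, adjusted p 0.00838), and Ctsb (0.54 ± 0.11, adjusted p 0.0309). Its adjusted p was 3.63e-09 (adjusted p = 0.199 with an estimated correlation). Igf1 and Csf1 were the 2 of 19 secreted growth factors that rose (2 over the list alone; list adjusted p 0.00993, adjusted p = 0.0808 with an estimated correlation).

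Other groups ran the opposite way at P7, in 4 lists that did not pass with an estimated correlation (adjusted p 0.0776 to 0.533). Homeostatic microglial genes had a median of -0.29 with 0 of 22 members called over all genes and 8 lower over the list alone. The list adjusted p was 8.05e-11. P2ry12 differed by -0.31 ± 0.12 (adjusted p 0.493) and Tmem119 by -0.65 ± 0.22 (adjusted p 0.394). Cell cycle genes had a median of -0.46 with 0 of 31 called and 3 lower over the list alone (1.42e-18). The proliferation gene Mki67 differed by -0.49 ± 0.22 (adjusted p 0.676). Sterol synthesis had a median of -0.21 (-0.37, -0.14 and -0.12 without cortex replicates 1, 2 and 3), 0 of 16 members called and an adjusted p of 0.000337. Purinergic and chemosensing receptors had -0.15, 0 of 17 called and 0.00448. The chemokine genes Ccl3 (1.40 ± 0.28, adjusted p 0.0267) and Ccl4 (0.75 ± 0.16, adjusted p 0.0397), the complement gene C2 (1.58 ± 0.26, adjusted p 0.00511) and the transcription factor gene Egr2 (1.19 ± 0.20, adjusted p 0.00658) rose. Their lists did not pass (inflammatory 2 of 20 higher, adjusted p 0.593; complement 1 of 12, adjusted p 0.567; immediate early and heat shock 1 of 22, adjusted p 0.344), with 2 members of each higher over the list alone. Interferon response, antigen presentation, extracellular matrix and oxidative phosphorylation genes had adjusted p-values of 0.567, 0.443, 0.129 and 0.0578.

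Among markers of other cells at P7, Folr2, typical of border-associated macrophages, rose by 1.95 ± 0.22 (adjusted p 9.05e-05), 1 of 11 (2 over the list alone) in a list with a median of 0.02 and an adjusted p of 0.224. Neuron markers had a median of -0.10, 0 of 14 called (2 lower over the list alone) and an adjusted p of 0.0335 (adjusted p = 0.479 with an estimated correlation). The lists for oligodendrocytes, their precursors, astrocytes, endothelial and mural cells, monocytes, neutrophils, lymphocytes and erythroid cells had adjusted p-values of 0.722, 0.553, 0.695, 0.443, 0.567, 0.0857, 0.878 and 0.867. Corpus callosum replicate 1 stood out with an Itgax level of 9.80, against 8.30 and 8.43 on replicates 2 and 3, and with a mean of 5.57 over the neutrophil markers, against 4.94 on each of the others. Without that array 48 genes were called, and the medians of the cell cycle and homeostatic lists were -0.21 and -0.19. Without cortex replicates 1, 2 or 3 there were 52, 55 and 60. Each of Apoc1, Atp6v0d2, C2, Cd200r4, Clec7a, Csf1, Fabp5, Folr2, Gpnmb, Hpse, Igf1, Itgax and Tnfsf18 kept its call whichever of the 6 arrays was left out. The call of Egr2 ended without cortex replicate 1 (adjusted p 0.0603, range over alternatives 0.00113 to 0.126). Those of Tpi1 (0.0709 and 0.0746, range 0.000683 to 0.0746) and Lipa (0.0906 and 0.0967, range 0.00092 to 0.0967) ended without cortex or corpus callosum replicate 1. Pgk1 (up to 0.113, the highest over its alternatives, lowest 0.00176) and Pgam1 (up to 0.126, lowest 0.00339) were lost without these or cortex replicate 2. Plin2 (up to 0.101, lowest 0.000485) was lost without corpus callosum replicate 1 or cortex replicate 2 or 3. Ccl3 (up to 0.256, lowest 0.00113) was lost without corpus callosum replicate 1 or any cortex array, and Ccl4 (up to 0.344, lowest 0.0125) without these or corpus callosum replicate 3. Zfp975 (up to 0.183, lowest 0.00248) was lost without any array but corpus callosum replicate 3, and Ctsb (up to 0.23, lowest 0.0019) without any of the 6. The list of neuron markers lost its call without cortex replicate 1 or 3 or corpus callosum replicate 2 (0.0834, 0.0571 and 0.2, range 0.00557 to 0.479). That of the purinergic receptors did so without corpus callosum replicate 1 (0.0971, range 0.00059 to 0.533).

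**Figure D2:**
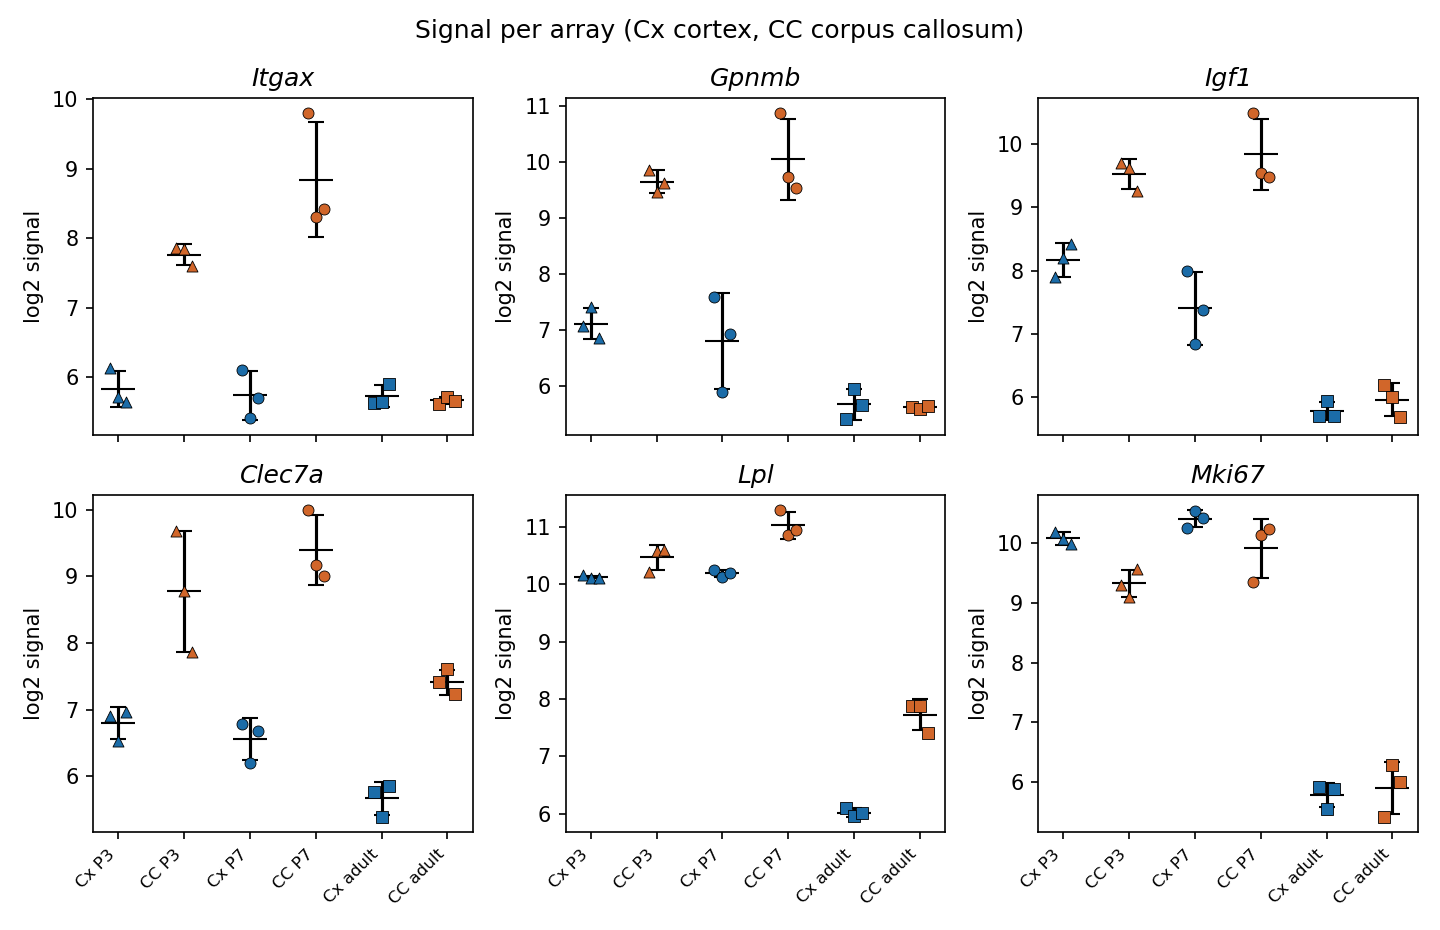
Signal in log2 units (vertical axis) of 6 genes on each of the 18 arrays by group (horizontal axis, Cx cortex and CC corpus callosum); points are arrays, horizontal bars group means and error bars standard deviations of 3 arrays. Itgax averages 8.84 in corpus callosum and 5.74 in cortex at P7 but 5.67 and 5.73 in the adult.

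The same regional question was asked at P3. Hpse was 4.57-fold higher in corpus callosum (2.19 ± 0.20, adjusted p 7.35e-05), Gpnmb 5.77-fold (2.53 ± 0.34, adjusted p 0.00187). Itgax was 3.83-fold (1.94 ± 0.28, adjusted p 0.00368) and Ccl5, a chemokine gene, 3.64-fold higher (1.86 ± 0.24, adjusted p 0.00183). Atp6v0d2 (2.81 ± 0.46, adjusted p 0.00749) rose from 4.52 ± 0.18 to 7.33 ± 1.31 and Clec7a (1.98 ± 0.33, adjusted p 0.00834) from 6.80 ± 0.24 to 8.78 ± 0.91. Igf1 (1.35 ± 0.27, adjusted p 0.031) rose from 8.17 to 9.53. The membrane protein gene Ms4a4a (1.87 ± 0.38, adjusted p 0.0334) and the mitophagy gene Bnip3 (1.75 ± 0.28, adjusted p 0.0074) also rose. Lower in corpus callosum were the growth cone gene Gap43 (-1.27 ± 0.18, adjusted p 0.00406), the imprinted non-coding RNA Meg3 (-1.32 ± 0.21, adjusted p 0.0074) and Gpm6a (-1.13 ± 0.20, adjusted p 0.0119). So were the somatostatin gene Sst (-1.04 ± 0.21, adjusted p 0.034), the sodium channel gene Scn2a (-1.03 ± 0.16, adjusted p 0.00726) and Arpp21 (-0.95 ± 0.15, adjusted p 0.0074). Ptprk (-1.11, adjusted p 0.037) and Taf1d (-1.06, adjusted p 0.0137) were lower as well. In total 112 genes differed, 78 higher and 34 lower, or 58 higher and 47 lower when the arrays were quantile-normalized again. All 112 had completely separated arrays, as did 15.8% of all genes. The genes higher at P3 and at P7 shared 36 members, against 0.348 for independent lists (hypergeometric p 3.28e-66). All 99 genes higher at P7 were also above cortex at P3, with a median of 0.71. Across all 22180 genes, which are not independent replicates, the regional differences at P3 and P7 correlated with r = 0.35 (rho 0.21).

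Of the axon tract and CD11c-type list, 9 of 23 members rose at P3 (18 over the list alone). The list had a median of 0.61 and an adjusted p of 1.68e-23 (adjusted p = 0.0131 with an estimated correlation). The other lists that passed with the preset correlation did not pass with an estimated one (adjusted p 0.0556 to 0.369). Lipid handling had 4 of 15 higher (8 over the list alone), with Apoc1 at 1.53 ± 0.25, Fabp5 at 1.23 ± 0.26 and Plin2 at 0.92 ± 0.19. Its adjusted p was 4.11e-08. Glycolysis had 2 of 13 higher, Tpi1 (1.06 ± 0.20) and Pgk1 (0.95 ± 0.17), and 8 higher and 1 lower over the list alone. Its adjusted p was 9.9e-08. Lysosomal genes had 1 of 23 higher, Lipa (0.77 ± 0.15), and 4 over the list alone (5.72e-07). Cell cycle genes had a median of -0.40 with 0 of 31 called and 3 lower over the list alone (3.59e-13). Mki67 differed by -0.75 ± 0.22 (adjusted p 0.138). Homeostatic genes had a median of -0.16 (-0.10 without corpus callosum replicate 1), 0 of 22 called and 3 lower over the list alone (0.000622). P2ry12 differed by -0.24 ± 0.12 (adjusted p 0.414) and Tmem119 by -0.52 ± 0.22 (adjusted p 0.332). Antigen presentation had a median of 0.16, 0 of 17 called and 1 higher over the list alone (0.00229).

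Markers of other cells moved with these groups at P3, in 4 lists that did not pass with an estimated correlation (adjusted p 0.153 to 0.162). The neuron list, with Gap43 and Meg3 as 2 of 14 members lower (2 over the list alone), had an adjusted p of 0.000601. Its array means were 5.97 to 6.25 in cortex and 5.54 to 5.94 in corpus callosum. Border-associated macrophage markers had 2 of 11 higher, Folr2 (1.63 ± 0.22, adjusted p 0.00187) and Ms4a7 (1.53 ± 0.29, adjusted p 0.0201), and 2 over the list alone. The list had an adjusted p of 0.00222. Monocyte markers had 1 of 10 higher, Lyz2 (0.90 ± 0.19, adjusted p 0.0384), and 2 higher and 1 lower over the list alone, with a list adjusted p of 0.0186. The endothelial and mural list had a median of -0.21 (-0.32 without corpus callosum replicate 2 and -0.14 without cortex replicate 3) with 0 of 13 called and 0.0186. Corpus callosum replicate 3 had the highest means of all arrays for the border-associated macrophage (7.34), monocyte (6.72) and neutrophil (6.05) markers. Without it the border-associated macrophage, monocyte, endothelial and mural and antigen presentation lists no longer passed, and the medians of the neuron and lysosome lists, -0.21 and 0.17 with it, were -0.10 and 0.09. The lysosome median was 0.26 without cortex replicate 3. The adjusted p was 0.199 for border-associated macrophages (range over alternatives 1.28e-05 to 0.9), 0.285 for monocytes (0.00417 to 0.581) and 0.133 for antigen presentation (0.000873 to 0.481). For endothelial and mural markers it was 0.133 (0.00444 to 0.347), and 0.232 without cortex replicate 3. Without cortex replicates 1 or 2 the comparison called 55 and 29 genes. With the neuron marker mean as a covariate, an alternative chosen after the data were seen, it called 14. That mean did not overlap between the regions at P3, so part of this loss follows from its tie to the region. Ccl5 (range over alternatives 0.000449 to 0.0158), Hpse (9.27e-06 to 0.0021) and Itgax (0.00054 to 0.0271) passed under every alternative. Arpp21, Folr2, Gap43, Gpnmb and Scn2a passed whichever array was left out but not under every alternative (highest adjusted p 0.24, 0.0557, 0.166, 0.0555 and 0.111). Leaving out cortex replicate 2 alone ended the calls of Apoc1 (0.0504, range 0.000473 to 0.0561), Atp6v0d2 (0.0504, range 0.000123 to 0.142) and Meg3 (0.0538, range 0.00257 to 0.238). It also ended those of Bnip3 (0.0542, range 0.00166 to 0.197), Clec7a (0.0586, range 0.000911 to 0.144) and Pgk1 (0.066, range 0.00421 to 0.249). Igf1 was lost without corpus callosum or cortex replicate 1 or 2 (0.0647 to 0.142, range 0.00783 to 0.142), and Gpm6a without cortex replicate 1 or 2 (0.077 and 0.0586, range 0.0058 to 0.305). Tpi1 was lost without these or corpus callosum replicate 3 (up to 0.11, range 0.00812 to 0.331) and Lipa without these or corpus callosum replicate 2 (up to 0.112, range 0.00713 to 0.146). Ms4a4a was lost without any cortex array (up to 0.116, range 0.00282 to 0.464). Ms4a7 was lost without corpus callosum replicate 1 or cortex replicate 1 or 3 (up to 0.109, range 0.00365 to 0.263) and Ptprk without corpus callosum replicate 1 or 3 or cortex replicate 1 (up to 0.153, range 0.0215 to 0.482). Taf1d was lost without corpus callosum replicate 1 or cortex replicate 2 or 3 (up to 0.0668, range 0.00479 to 0.124), and Sst without any array but corpus callosum replicate 2 (up to 0.14, range 0.0138 to 0.197). Fabp5 (up to 0.159, range 0.0168 to 0.273), Plin2 (up to 0.128, range 0.016 to 0.278) and Lyz2 (up to 0.136, range 0.00989 to 0.192) were lost without any of the 6.

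In the adult the regional comparison asks whether the difference persists once myelin is in place. Lpl, which encodes lipoprotein lipase, was the 1 gene called, 3.26-fold higher in corpus callosum (1.70 ± 0.15, adjusted p 1.72e-05), at 7.72 ± 0.27 against 6.02 ± 0.07. It passed under every alternative (adjusted p 6.88e-07 to 0.0193) and was also higher in corpus callosum at P7 (0.84 ± 0.15, adjusted p 0.0081). Of the genes with the next smallest p, which did not pass, Clec7a differed by 1.74 ± 0.33, Emp3 by 0.86 ± 0.15, Cypt12 by 0.80 and Armcx3 by -0.61, each with an adjusted p of 0.236. Of the genes that led at P7, Itgax gave -0.06 ± 0.28 (adjusted p 0.971), with 5.67 ± 0.05 in corpus callosum and 5.73 ± 0.16 in cortex. Igf1 gave 0.18 ± 0.27 (adjusted p 0.897). P2ry12 (0.01 ± 0.12), Tmem119 (-0.13 ± 0.22) and Mki67 (0.12 ± 0.22) did not pass either. Of the 99 genes higher at P7, 43 were above cortex in the adult, with a median of -0.03. Complete separation was seen for 12.8% of all genes. At an unadjusted p under 0.05 limma gave 1888 genes. Without corpus callosum replicate 3 there were 3 called genes.

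The axon tract and CD11c-type list passed in the adult with 1 of 23 members higher (3 over the list alone), a median of 0.18 (0.10 without cortex replicate 3 and 0.11 without corpus callosum replicate 2) and an adjusted p of 0.00297. With an estimated correlation none of the 4 lists that passed in the adult did so (adjusted p 0.426 to 0.862). Interferon response genes had a median of -0.24 with 0 of 16 called and an adjusted p of 0.00297. They were at -0.13 and 0.0908 without cortex replicate 2 (range 0.000568 to 0.426). Glycolysis had -0.23 (-0.15 without corpus callosum replicate 1) and 0.0335. It was lost without cortex replicate 1 or 2 or corpus callosum replicate 1 or 2 (0.06, 0.121, 0.158 and 0.0804, range 0.0288 to 0.862). Oxidative phosphorylation had -0.11 (-0.22 without cortex replicate 1 and -0.06 without corpus callosum replicate 1) and 0.0275. That call was lost without cortex replicate 2 or 3 or corpus callosum replicate 1 or 2 (0.13, 0.109, 0.137 and 0.154, range 0.0053 to 0.768). Lipid handling, the list that also holds Lpl, had a median of 0.11 and an adjusted p of 0.0751.

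**Figure D3:**
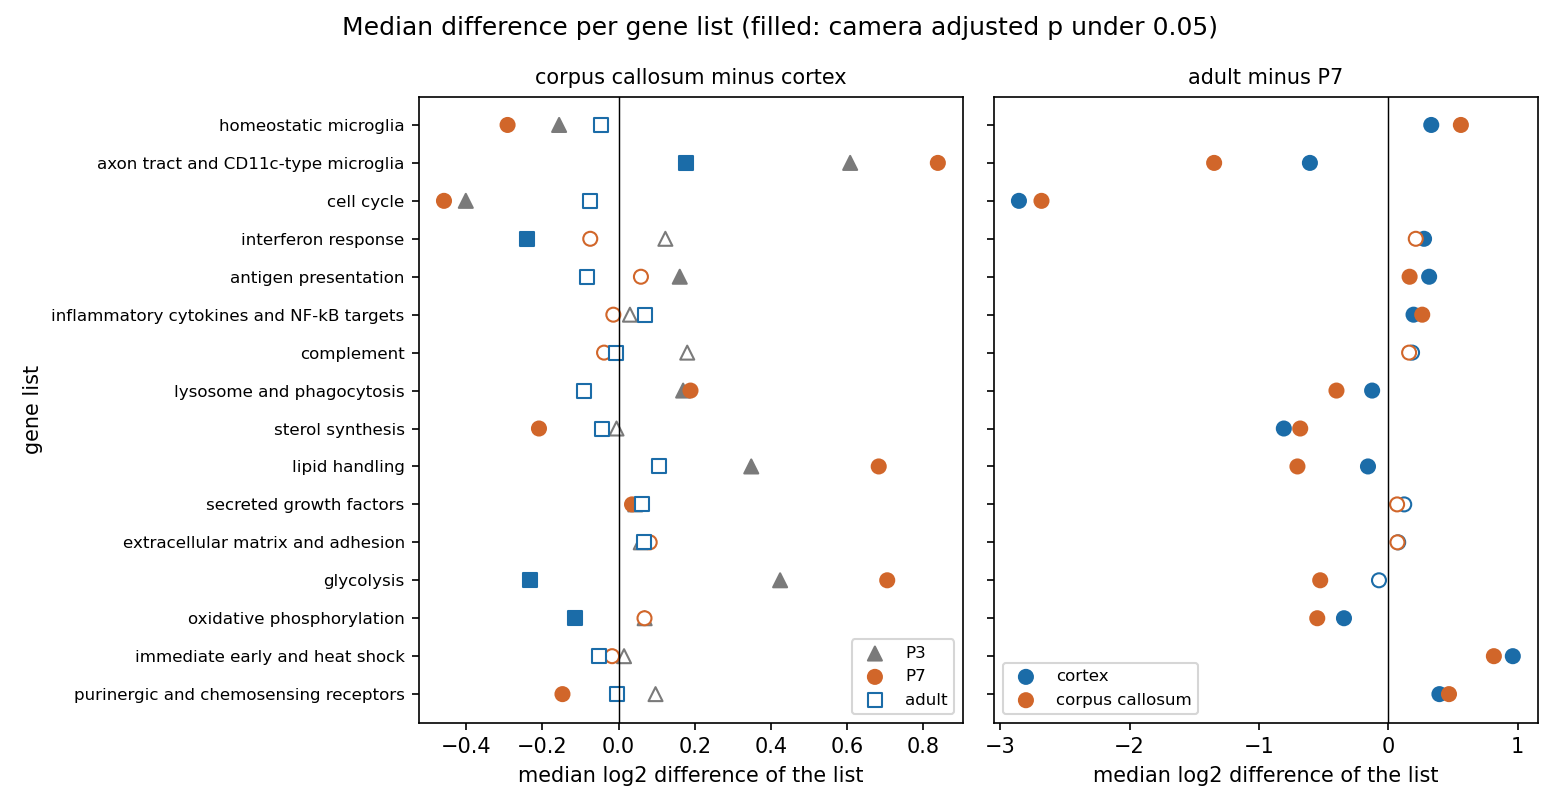
Median log2 difference (horizontal axis) of the 16 gene lists (vertical axis) for corpus callosum minus cortex at each age (left) and for adult minus P7 in each region (right); symbols are list medians and are filled where camera with the preset correlation gave an adjusted p under 0.05. The axon tract and CD11c-type list lies at 0.61, 0.84 and 0.18 on the left and at -0.61 and -1.35 on the right.

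Whether the regional difference itself changed with age was tested directly. From P7 to adult it fell by 3.17 ± 0.39 for Itgax (adjusted p 0.00211). For Hpse it fell by 2.71 ± 0.29 (adjusted p 0.00059), and for Gpnmb it fell by 3.29 ± 0.48 (adjusted p 0.00872). These 3 calls held under every alternative, with highest adjusted p-values of 0.0329, 0.0108 and 0.0386. Atp6v0d2 (-4.19 ± 0.65, adjusted p 0.00933) and the chemokine gene Ccl6 (-2.01 ± 0.31, adjusted p 0.00872) fell as well. Each was at 0.0858 with both adult replicate 1 arrays left out, an alternative chosen after the data were seen (ranges 0.0017 to 0.0858 and 0.00219 to 0.0858). Igf1 gave -2.26 ± 0.38 (adjusted p 0.0189) and was lost without cortex P7 replicate 2 or 3, cortex adult replicate 2 or 3, or corpus callosum adult replicate 2 (0.051 to 0.0741, range 0.00421 to 0.0776). Clec7a, at -1.09 ± 0.47, did not pass (adjusted p 0.61), and neither did Lpl (0.87, adjusted p 0.122). In all 45 genes differed, 1 higher and 44 lower. The axon tract and CD11c-type list fell with 5 of 23 members lower (2 higher and 15 lower over the list alone). It had a median of -0.87 and an adjusted p of 9.78e-20 (adjusted p = 0.0261 with an estimated correlation). Glycolysis had 3 of 13 lower (7 over the list alone), a median of -0.89 and 6.82e-12 (adjusted p = 0.103 with an estimated correlation). The count was 21, 12 and 13 without cortex P7 replicates 1, 2 and 3 and 20 without corpus callosum P7 replicate 1. It was 25, 14 and 13 without cortex adult replicates 1, 2 and 3, 18 and 17 without corpus callosum adult replicates 1 and 2, and 10 without both adult replicate 1 arrays.

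Between P3 and adult 40 genes differed in their regional difference, 13 higher and 27 lower (7 and 6 after renewed quantile normalization, 12 and 68 after median centring). Hpse gave -2.24 ± 0.29 (adjusted p 0.00907), lost without corpus callosum adult replicate 2 and with both adult replicate 1 arrays left out (range 0.00188 to 0.0536). The count was 0 without corpus callosum adult replicate 2, 1 without cortex adult replicate 2 or 3 or cortex P3 replicate 1 or 2, and 3 without corpus callosum adult replicate 1. It was 16, 24 and 13 without corpus callosum P3 replicates 1, 2 and 3, 12 without cortex P3 replicate 3, and 101 without corpus callosum adult replicate 3. Between P3 and P7 limma called 0 genes, with 1260 at an unadjusted p under 0.05, and 1 without cortex P7 replicate 3. The 5 genes with the smallest p, none of which passed, were 1700080N15Rik (1.63 ± 0.25, adjusted p 0.0952), Arpp21 (1.03), Gm9839 (0.79), Mir132 (0.97) and A230004M16Rik (1.13), each of the last 4 with an adjusted p of 0.868. Itgax gave 1.17 ± 0.39 and Igf1 1.08 ± 0.38, both with an adjusted p of 0.868.

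Adult and P7 microglia were compared within each region. Isolation effects that differ with age were not tested. In cortex the linker histone gene H1f5 was lower in the adult (-7.16 ± 0.40, adjusted p 7.04e-10). Rrm2, a subunit of ribonucleotide reductase (-5.31 ± 0.22, adjusted p 3.22e-11), Top2a, a topoisomerase of dividing cells (-4.99 ± 0.23, adjusted p 7.69e-11), and Mki67 (-4.61 ± 0.22, adjusted p 1.19e-10) fell with it. The mitotic genes Knl1 (-4.52), Bub1 (-4.48), Ube2c (-4.42) and Depdc1a (-4.25) fell too. Upk1b (4.32 ± 0.25, adjusted p 1.06e-09), the interleukin 7 receptor gene Il7r (3.84 ± 0.30, adjusted p 5.13e-08) and Csmd3 (3.59 ± 0.16) rose. So did the heat shock genes Hspa1a (3.32 ± 0.44) and Hspa1b (2.51 ± 0.28), Rgs1 (2.79), Btg2 (2.28 ± 0.27) and Gprasp2 (2.02). In corpus callosum H1f5 (-6.78 ± 0.40, adjusted p 1.92e-09), Rrm2 (-5.22 ± 0.22), Top2a (-4.45 ± 0.23), Ube2c (-4.08) and Mki67 (from 9.90 ± 0.49 to 5.91 ± 0.44, adjusted p 9.27e-10) fell too. So did Atp6v0d2 (-5.03 ± 0.46, adjusted p 3.29e-07), Fabp5 (-4.84 ± 0.26, adjusted p 6.87e-10), Mrc1 (-4.44 ± 0.27, adjusted p 3.07e-09) and Gpnmb (-4.42 ± 0.34, adjusted p 4.3e-08). Il7r (from 4.69 ± 0.72 to 8.70 ± 0.16, adjusted p 3.83e-08), Upk1b (3.92 ± 0.25), Csmd3 (3.53), Rgs1 (2.87), Hspa1a (2.80 ± 0.44), Btg2 (2.62 ± 0.27), Kcnrg (2.55) and Neurl3 (2.32) rose there. In cortex 2264 genes differed (899 higher, 1365 lower) and in corpus callosum 3822 (1454 higher, 2368 lower, or 1887 and 2025 after renewed quantile normalization). Of these, 2248 and 3759 had completely separated arrays, as did 27.3% and 34.6% of all genes. The regions shared 598 higher and 1169 lower genes, against 58.9 and 146 for independent lists. There were 3 genes called in opposite directions.

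Igf1 fell by 3.88 ± 0.27 in corpus callosum (adjusted p 1.21e-08) and by 1.62 ± 0.27 in cortex (adjusted p 0.000398). Itgax fell by 3.18 ± 0.28 in corpus callosum (adjusted p 1.88e-07) and differed by -0.01 ± 0.28 in cortex (adjusted p 0.989). Clec7a fell by 1.98 ± 0.33 in corpus callosum (adjusted p 0.000276) and differed by -0.88 in cortex (adjusted p 0.114). The axon tract and CD11c-type list fell in corpus callosum with 20 of 23 members lower and 1 higher, both over all genes and over the list alone. It had a median of -1.35 and an adjusted p of 6.84e-23 (adjusted p = 0.00768 with an estimated correlation). In cortex 11 members fell and 1 rose (14 and 2 over the list alone). The median was -0.61 and 2.16e-10 (adjusted p = 0.0545 with an estimated correlation). Lpl fell by 4.17 ± 0.15, Fabp5 by 3.44 ± 0.26 and the galectin gene Lgals1 by 2.10 ± 0.17. All 31 cell cycle genes fell in both regions, both over all genes and over the list alone. The medians were -2.86 and -2.68, with adjusted p-values of 8.04e-79 and 2.53e-53 (adjusted p = 0.00114 and 0.00666 with an estimated correlation).

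Homeostatic genes rose toward the adult with 9 of 22 members in cortex and 15 in corpus callosum (12 and 17 over the list alone). The medians were 0.33 and 0.56, with adjusted p-values of 2.11e-06 and 1.73e-08 (adjusted p = 0.207 and 0.136 with an estimated correlation). Selplg rose by 1.57 ± 0.19 and 2.28 ± 0.19, Tmem119 by 1.03 ± 0.22 (adjusted p 0.00413) and 1.56 ± 0.22 (adjusted p 5.77e-05). The integrin gene Itgb5, of the axon tract and CD11c-type list, rose by 0.67 ± 0.15 and 1.14 ± 0.15. The fructose transporter gene Slc2a5 rose by 0.92 in cortex, and Tgfbr1, a receptor of transforming growth factor beta, by 1.40 ± 0.12 in corpus callosum. P2ry12 rose by 0.47 ± 0.12 in corpus callosum (adjusted p 0.00842, but 0.0638 without corpus callosum P7 replicate 1, range 0.000777 to 0.0638) and differed by 0.15 in cortex (adjusted p 0.564). Purinergic and chemosensing receptors rose with 7 of 17 members and fell with 1 in cortex (9 and 1 over the list alone). They rose with 11 in corpus callosum (11 higher and 1 lower over the list alone). The adjusted p-values were 3.96e-06 and 3.01e-06 (adjusted p = 0.207 and 0.227 with an estimated correlation). Tlr3, a receptor of double-stranded RNA, rose by 1.51 ± 0.18 and 1.78 ± 0.18, the interleukin 10 receptor gene Il10ra by 1.11 and 1.42, and Csf3r by 1.28 ± 0.14 in cortex, while Ccr1 fell by 1.41 there. Immediate early and heat shock genes rose with 12 of 22 members in each region, with 1 lower in corpus callosum, Egr2 (-1.22 ± 0.20). Adjusted over the list alone these were 13 in each, and 1 lower in corpus callosum. Their adjusted p-values were 4.48e-11 and 3.09e-06 (adjusted p = 0.0461 and 0.136 with an estimated correlation).

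Immune groups changed between P7 and adult as well. Antigen presentation rose with 5 of 17 members in cortex and 3 in corpus callosum (7 and 3 over the list alone). H2-DMa gave 0.87 ± 0.18 and 1.07 ± 0.18, and the list had adjusted p-values of 4.48e-05 and 0.036 (adjusted p = 0.0582 and 0.291 with an estimated correlation). In corpus callosum the list was lost without P7 replicate 3 or adult replicate 3 (0.0689 and 0.0833, range 0.00594 to 0.291). Inflammatory genes rose with 5 of 20 members in cortex, and with 6 in corpus callosum where 1 fell (9 higher and 1 lower, and 7 higher and 1 lower, over the list alone). Il6 rose by 1.43 ± 0.21 and 1.48 ± 0.21 and Il1a by 1.03 ± 0.19 and 1.54 ± 0.19, whereas Ccl3 fell by 1.58 ± 0.28 in corpus callosum. The list's adjusted p-values were 0.0254 and 0.0383 (adjusted p = 0.427 and 0.475 with an estimated correlation). The cortex call was lost without P7 replicate 1 or adult replicate 1 (0.144 and 0.124, range 0.011 to 0.427) and that in corpus callosum without P7 replicate 2 or adult replicate 1 or 2 (0.0828, 0.0721 and 0.068, range 0.00547 to 0.475). Interferon response genes rose with 5 of 16 members in cortex (5 over the list alone). The list had an adjusted p of 0.00127 (adjusted p = 0.0787 with an estimated correlation). Ddx58, a cytosolic RNA sensor, rose by 0.96 ± 0.15 and Usp18 by 0.90 ± 0.12. In corpus callosum the list did not pass (adjusted p 0.167). Complement genes did not pass as a list (0.0881 and 0.472). The integrin genes Itgb2 (0.85 and 0.86) and Itgam (0.61 and 0.84) rose in both regions, and C2 (-1.34) and C3ar1 (-0.65) fell in corpus callosum.

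Metabolic groups fell toward the adult. Sterol synthesis fell with 11 of 16 members in cortex and 10 in corpus callosum (11 and 10 over the list alone). The adjusted p-values were 5.98e-12 and 2.83e-07 (adjusted p = 0.0351 and 0.0819 with an estimated correlation). Sqle, squalene epoxidase, gave -1.96 ± 0.21 and -1.37 ± 0.21 and Cyp51 gave -1.55 ± 0.18 and -1.25 ± 0.18. Lipid handling fell with 6 of 15 members in cortex, where Abcg1 rose, and with 10 in corpus callosum (7 lower and 1 higher, and 11 lower, over the list alone). Its adjusted p-values were 5.42e-05 and 1.76e-10 (adjusted p = 0.0787 and 0.0115 with an estimated correlation). Lpl fell by 3.30 ± 0.15 and Apoc1 by 3.40 ± 0.25 in corpus callosum. The small rise of Abcg1 (0.55, adjusted p 0.0377) was lost without cortex P7 replicate 2 or 3 or adult replicate 2 or 3 (0.108 to 0.163). Oxidative phosphorylation fell with 6 and 10 of 17 members (9 and 15 over the list alone). The adjusted p-values were 8.59e-09 and 5.12e-11 (adjusted p = 0.0369 and 0.0115 with an estimated correlation), and Cox4i1 gave -0.84 ± 0.11 and -1.32 ± 0.11. Glycolysis fell in corpus callosum with 6 of 13 members lower and Hk1 higher (9 and 1 over the list alone). The adjusted p was 8.61e-07 (adjusted p = 0.136 with an estimated correlation), with Pgk1 at -2.28 ± 0.17, Tpi1 at -2.05 ± 0.20 and Pkm at -1.64 ± 0.20. In cortex the list did not pass (adjusted p 0.464). The rise of Hk1 (0.45, adjusted p 0.0271) was lost without P7 replicate 1 or 3 or adult replicate 2 or 3 (up to 0.122, range 0.00284 to 0.122). Lysosomal genes fell with 12 of 23 members and rose with 2 in corpus callosum, both over all genes and over the list alone. The list had an adjusted p of 8.61e-07 (adjusted p = 0.228 with an estimated correlation). In cortex 5 fell and 2 rose (7 and 2 over the list alone). The adjusted p was 0.0318 (adjusted p = 0.637 with an estimated correlation), a call lost without P7 replicate 3 or adult replicate 1 (0.0629 and 0.25, range 0.0118 to 0.637). Gas6, a bridging molecule for the uptake of dying cells, fell by 1.92 ± 0.12 in cortex and fell by 2.27 ± 0.12 in corpus callosum. Its receptor gene Mertk rose by 1.06 ± 0.13 and 0.82. The secreted growth factor and extracellular matrix lists did not pass (0.72 and 0.717; 0.149 and 0.717). Pdgfb rose by 1.02 ± 0.17 and 0.87, the matrix protease gene Mmp14 rose by 1.45 ± 0.19 and 1.03, and Csf1 fell by 2.61 ± 0.28 in corpus callosum.

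Of the markers of other cells, the border-associated macrophage list fell with 4 of 11 members in cortex and 6 in corpus callosum (4 and 6 over the list alone). Its adjusted p-values were 2.13e-05 and 5.78e-05 (adjusted p = 0.0588 and 0.0956 with an estimated correlation). Mrc1, the mannose receptor, fell by 4.23 ± 0.27 in cortex, from 11.05 to 6.82. Pf4 gave -2.43 ± 0.35 and -1.91 ± 0.35, and Folr2 fell by 2.66 ± 0.22 in corpus callosum. The neuron (0.0612 and 0.909), astrocyte (0.805 and 0.677), oligodendrocyte (0.72 and 0.534), monocyte (0.126 and 0.44) and lymphocyte (0.805 and 0.5) lists did not pass. Within them Gap43 fell by 1.56 ± 0.18 in cortex, the radial glia gene Fabp7 fell by 2.82 ± 0.42 and fell by 2.24 ± 0.42, and the glutamate transporter gene Slc1a3 rose by 1.79 ± 0.22 and 0.96 ± 0.22.

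P7 was compared with P3 in each region for the earliest change, with the limit that the P3 arrays form an array set of their own, so that age and array set cannot be told apart. In cortex the largest falls were those of Ptprz1, a phosphatase of glial precursors (-2.92 ± 0.43, adjusted p 0.00242), the surface protein gene Cd24a (-2.57 ± 0.50, adjusted p 0.0183), the imprinted RNA Ipw (-2.25, adjusted p 0.0255) and AF357425 (-2.13, adjusted p 0.0204). They were followed by Fabp7 (-2.12 ± 0.42, adjusted p 0.0204), Syt4 (-2.04, adjusted p 0.0345), Meg3 (-1.83 ± 0.21, adjusted p 0.000367) and Gpm6a (-1.80 ± 0.20, adjusted p 0.000264). Rcn1 (1.30, adjusted p 0.0255), H2bc14 (1.04, adjusted p 0.0166), Cyp51 (1.02 ± 0.18, adjusted p 0.00723), the kinetochore gene Cenpf (0.93 ± 0.17, adjusted p 0.01) and Fdps (0.91 ± 0.18, adjusted p 0.0204) rose. So did Gimap9 (0.91), Spdl1 (0.89) and the proteasome activator gene Psme3 (0.84 ± 0.14, adjusted p 0.00686). The neuron list fell with 3 of 14 members (5 over the list alone; 1.99e-05). Gap43 fell by 1.12 ± 0.18, and Dcx, a gene of migrating neurons, fell by 0.65 ± 0.13. The astrocyte (1 of 14, 5 over the list alone; 0.000141), oligodendrocyte precursor (1 of 12, 3 alone; 0.00105) and lipid handling lists (1 of 15, 2 alone; 0.00467) fell too. Sterol synthesis (4 of 16, 9 alone; 2.35e-07), cell cycle (1 of 31, 2 alone; 7.1e-07), homeostatic (1 of 22, 1 alone; 3.39e-06), purinergic receptor (0 of 17, 0 alone; 0.00282) and border-associated macrophage genes (0 of 11, 0 alone; 0.0435) rose. With an estimated correlation none of these 9 lists passed (adjusted p 0.224 to 0.581). Lipid handling was lost without P3 replicate 3 (0.0671), and border-associated macrophages without P7 replicate 1 or P3 replicate 1 or 3 (0.236, 0.152 and 0.222). Igf1 (-0.77, adjusted p 0.21), Itgax (-0.09, adjusted p 0.928), Clec7a (-0.25, adjusted p 0.819) and Mki67 (0.32, adjusted p 0.576) did not pass. In total 196 genes differed, 62 higher and 134 lower (87 and 122 after median centring, 90 and 51 without dim probe sets). All had completely separated arrays, as had 21.3% of all genes. The count was 114, 74 and 75 without P7 replicates 1, 2 and 3 and 72 and 115 without P3 replicates 1 and 2. It was 0 with the neuron marker mean as a covariate. Apoc1 (-1.59 ± 0.25, adjusted p 0.00355), Gap43, Gpm6a, Meg3, the glycolytic gene Pfkp (-1.13 ± 0.17, adjusted p 0.00309), Psme3 and Ptprz1 were the 7 of 24 named genes that kept their call whichever array was left out. Cyp51 was lost without P7 replicate 3 (0.0599, range 0.000661 to 0.529) and Cenpf without P7 replicate 2 or P3 replicate 1 (0.0631 and 0.0522, range 0.00419 to 0.354). AF357425 was lost without P7 replicate 2 or 3 or P3 replicate 1 (up to 0.137, range 0.00234 to 0.732). Cd24a was lost without any P7 array or P3 replicate 1 (0.0527, 0.0727, 0.0798 and 0.11, range 0.000829 to 0.841) and Dcx without any P7 array or P3 replicate 3 (up to 0.116, range 0.00332 to 0.641). Fabp7 was lost without P7 or P3 replicate 1 or 2 (up to 0.117, range 0.00219 to 0.831), and Ipw without P7 replicate 2 or 3 or P3 replicate 1 or 2 (up to 0.137, range 0.00182 to 0.853). Fdps was lost without P7 or P3 replicate 3 or 2 (up to 0.105, range 0.00229 to 0.125). Without P7 replicate 1 or 2 or P3 replicate 2 or 3, H2bc14 (up to 0.082, range 0.00192 to 0.247) and Gimap9 (up to 0.137, range 0.00841 to 0.196) were lost. Rcn1 (up to 0.131, range 0.00373 to 0.599) and Syt4 (up to 0.149, range 0.00354 to 0.774) were lost without any array but P3 replicate 3, and Spdl1 (up to 0.182, range 0.00588 to 0.579) without any but P7 replicate 1.

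In corpus callosum the histone genes H2ac15 (2.62 ± 0.43, adjusted p 0.0112) and H1f1 (2.40 ± 0.35, adjusted p 0.00658) had the largest rises from P3 to P7. They were followed by Adamts1 (1.32), the protease inhibitor gene Slpi (1.30 ± 0.22, adjusted p 0.0123), Slc36a4 (1.13), H2bc14 (1.08), Cyp51 (from 6.17 to 7.17, adjusted p 0.0172) and Plau (0.93). Ptprz1 (-2.56 ± 0.43, adjusted p 0.0123), Cd24a (-2.30), Ms4a4a (-2.09 ± 0.38, adjusted p 0.0178), Ccl5 (-1.86 ± 0.24, adjusted p 0.00368), Erdr1 (-1.64), Snhg14 (-1.53), Neurl3 (-1.38) and the growth factor gene Ptn (-1.36) fell. Inflammatory genes had 2 of 20 members lower, Ccl5 and Cxcl16 (-0.98), with 1 higher and 5 lower over the list alone, and a list adjusted p of 0.0605. The cell cycle (1 of 31, 2 over the list alone; 1.8e-06), sterol (1 of 16, 6 higher and 1 lower alone; 0.00265), axon tract and CD11c-type (1 of 23, 6 higher and 1 lower alone; 0.00743) and homeostatic lists (0 of 22, 1 alone; 0.0108) rose. The neuron (1 of 14, 5 alone; 0.00743) and astrocyte lists (0 of 14, 3 alone; 0.00363) fell. With an estimated correlation each of these 6 lists had an adjusted p of 0.631. The neuron list was lost without P7 replicate 2 or P3 replicate 1 (0.0558 and 0.0668, range 6.86e-05 to 0.756), the axon tract list without P7 replicate 1 (0.489) and the homeostatic list without P7 replicate 2 or 3 (0.106 and 0.112). The cell cycle median, 0.31, was 0.50 without P7 replicate 1 and 0.20 without P7 replicate 2 or 3. Itgax (1.08 ± 0.28, adjusted p 0.0773), Igf1 (0.31, adjusted p 0.653), Clec7a (0.61, adjusted p 0.427) and Mki67 (0.58, adjusted p 0.229) did not pass. In total 164 genes differed, 72 higher and 92 lower (105 and 102 after renewed quantile normalization, 174 and 127 without dim probe sets). All had completely separated arrays, as had 18.8% of all genes. The regions shared 18 higher and 27 lower genes, against 0.201 and 0.556 for independent lists. The count moved to 67, 21 and 13 without P7 replicates 1, 2 and 3 and to 35, 74 and 506 without P3 replicates 1, 2 and 3. Ccl5, H1f1 and the membrane protein gene Ms4a4c (-1.19 ± 0.19, adjusted p 0.0106) were the 3 of 22 named genes that kept their call whichever array was left out. Slpi was lost without P7 replicate 2 (0.05, range 0.00305 to 0.123) and Slc36a4 without P7 replicate 3 (0.0679, range 0.00236 to 0.123). H2ac15 (0.0581 and 0.0714, range 0.000907 to 0.145) and Ms4a4a (0.076 and 0.0794, range 0.00118 to 0.213) were lost without P7 replicate 2 or 3. Without these or P3 replicate 1, Cyp51 (up to 0.0827, range 0.0042 to 0.123) and Ptprz1 (up to 0.0682, range 7.82e-07 to 0.183) were lost. Without P7 replicate 2 or 3 or P3 replicate 2, Neurl3 (up to 0.0782, range 0.00136 to 0.145) and Ptn (up to 0.0794, range 0.00439 to 0.126) were lost. Without P7 replicate 2 or 3 or P3 replicate 1 or 2, Adamts1 (up to 0.1, range 0.00505 to 0.123) and Erdr1 (up to 0.195, range 0.0141 to 0.267) were lost. Snhg14 was lost without P7 or P3 replicate 1 or 2 (up to 0.073, range 0.00249 to 0.136). H2bc14 (up to 0.0794, lowest 0.00305) and Cxcl16 (up to 0.111, range 0.0147 to 0.146) were lost without any P7 array or P3 replicate 2, and Plau (up to 0.11, range 0.015 to 0.172) and Cd24a (up to 0.148, range 0.00397 to 0.295) without any array but P3 replicate 3.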

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

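Of the tests in this part, the 6 on the small number of adult differences, on the neuron transcripts and on the adult replicate 1 arrays were chosen only after the result was seen, as were the omission of both adult replicate 1 arrays, the neuron covariate and the splits without the common regional difference. The other splits of the arrays were planned.

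The regional difference changed with age for 45 genes between P7 and adult and for 40 between P3 and adult. Between P7 and adult it moved toward corpus callosum for H60b (1.47), a ligand of an activating receptor. It moved toward cortex for Atp6v0d2 (-4.19), Gpnmb (-3.29), Itgax (-3.17), Hpse (-2.71), Igf1 (-2.26), Cd200r4 (-2.19), Ccl6 (-2.01), Lag3 (-1.96), Apoc1 (-1.86), Tpi1 (-1.60), Folr2 (-1.56), Egr2 (-1.44), Pgk1 (-1.31) and Pgam1 (-1.16). Atp6v0d2, Ccl6, Gpnmb, Hpse and Itgax kept their call whichever of the 12 arrays was left out. The other 10 lost it without cortex adult replicate 3 and without 3 or more further arrays each. Their highest adjusted p over all alternatives was 0.0678 for Lag3, 0.0776 for Igf1, 0.0984 for Pgk1, 0.124 for Tpi1, 0.153 for Egr2, 0.154 for Pgam1, 0.162 for Apoc1 and Folr2, 0.177 for H60b and 0.242 for Cd200r4.

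Between P3 and adult it rose for Gap43 (1.56), Zdhhc2 (1.54), Taf1d (1.51), Lpl (1.37), Scn2a (1.23), Cntn5 (1.01), Mlip (0.96) and Krtap5-2 (0.93). It fell for Gpnmb (-2.58), Hpse (-2.24), Itgax (-2.00), Lag3 (-1.93), Ccl6 (-1.67), Tpi1 (-1.49), Pgk1 (-1.33), Gsto1 (-1.17) and Cst7 (-1.05). Each of these 17 genes was lost without corpus callosum adult replicate 2, and each but Hpse also without cortex adult replicate 2 or 3. The highest adjusted p over all alternatives was 0.0536 for Hpse and 0.0899 for Taf1d. It was 0.143 for Lpl, 0.168 for Itgax, 0.186 for Lag3 and Gsto1, 0.196 for Ccl6, and 0.207 for Gpnmb, Scn2a, Cst7 and Krtap5-2. For Cntn5, Gap43, Zdhhc2, Pgk1, Mlip and Tpi1 it was 0.209, 0.274, 0.274, 0.275, 0.294 and 0.346.

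Gene lists drew attention for the same reason. Between P3 and P7 these were the axon tract and CD11c-type list (median 0.38, 0.24 without corpus callosum P7 replicate 1), lipid handling (0.13), purinergic receptors (-0.19) and endothelial and mural markers (0.31, 0.19 without cortex P3 replicate 3). The lipid handling median was 0.20, 0.23, 0.23 and 0.07 without corpus callosum P7 or P3 replicate 3 or cortex P3 replicate 2 or 3. With an estimated correlation none of these 4 passed (0.685, 0.758, 0.758 and 0.352), and against the preset correlation 3 of them were lost without single arrays. Lipid handling was lost without corpus callosum P3 replicate 1 or 2 or P7 replicate 1 or cortex P3 or P7 replicate 3 (0.147, 0.076, 0.261, 0.236 and 0.172), purinergic receptors without corpus callosum P3 replicate 3 or P7 replicate 1 (0.134 and 0.0572), and endothelial and mural markers without corpus callosum or cortex P3 replicate 3 (0.0974 and 0.19). Between P7 and adult they were homeostatic microglia (0.25), the axon tract and CD11c-type list (-0.87), cell cycle (0.34, 0.17 without corpus callosum P7 replicate 1), lysosome (-0.24), lipid handling (-0.46), glycolysis (-0.89), oxidative phosphorylation (-0.23) and neuron markers (0.21). With an estimated correlation the axon tract and CD11c-type list passed (0.0261) and the other 7 did not (0.431, 0.397, 0.309, 0.106, 0.103, 0.309 and 0.397). Homeostatic microglia was lost without cortex adult replicate 1 (0.0797) and the neuron list without corpus callosum P7 replicate 2 (0.0832). Between P3 and adult they were the axon tract and CD11c-type list (-0.60), cell cycle (0.34), interferon response (-0.40, -0.24 without corpus callosum P3 replicate 2), antigen presentation (-0.17, -0.10 without cortex adult replicate 2), lysosome (-0.27, -0.17 without corpus callosum P3 replicate 3), lipid handling (-0.40), glycolysis (-0.72), oxidative phosphorylation (-0.22) and neuron markers (0.35, 0.23 without cortex P3 replicate 1). None of these 9 passed with an estimated correlation (0.317, 0.446, 0.317, 0.327, 0.426, 0.446, 0.317, 0.446 and 0.327). Antigen presentation was lost without corpus callosum P3 replicate 3 (0.0676). Lipid handling was lost without that array (0.257), corpus callosum adult replicate 1 or 3 (0.0554 and 0.0815), cortex P3 replicate 1 or 2 (0.0627 and 0.0641) or cortex adult replicate 2 or 3 (0.0674 and 0.0799). Oxidative phosphorylation was lost without corpus callosum P3 replicate 3 (0.0826), corpus callosum adult replicate 1 or 2 (0.071 and 0.0821), cortex P3 replicate 3 (0.0588) or cortex adult replicate 2 or 3 (0.0773 and 0.0631).

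Probe sets without a single gene symbol also held differences between the regions: 3 of 17824 at P3 (2 higher in corpus callosum, the largest by 3.20) and 3 at P7 (all 3 higher, the largest by 3.40).

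Other splits of the same arrays were fitted. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 112 and 1 genes between the regions at P3, 100 and 0 at P7, and 1 and 14 in the adult, where 3 of the 10 splits gave at least 1. For adult against P7 they gave 2264 and 0 in cortex and 3822 and 1 in corpus callosum. For P7 against P3 they gave 196 and 1 in cortex and 164 and 1 in corpus callosum. For the change of the regional difference 100 were fitted. Between P7 and adult 2 of 100 reached 45 genes and between P3 and adult 1 of 100 reached 40, and the highest other splits gave 84 and 12. Splits that mix the regions hold the regional difference as spread, so they were repeated with the part common to both ages taken out. Then 1 of 100 reached each count and the highest others gave 1 and 2. This does not exclude chance, as mixed splits still hold the change itself as spread. The counts were 10 and 0 without both adult replicate 1 arrays. The adult split with 14 genes sets corpus callosum adult replicates 1 and 2 and cortex adult replicate 1 against the other adult arrays, which points to a structure of the adult arrays that does not follow the region. The splits with 84 and 12 genes do the same but keep the regions whole at P7 or P3, so that regional difference adds to their counts. Between P3 and P7 all 100 splits gave at least the 0 genes that limma called, and 1 gave 439. That split keeps the regions whole at both ages and turns the direction at 1 of them, so it adds the 2 regional differences, and the structure it points to is the region itself.

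The first pattern weighed is that 1 gene differed between the regions in the adult against 100 at P7. A larger spread on the adult arrays could hide differences as large as those at P7, but the 99 genes higher at P7, with a median of 1.08 there, had an adult median of -0.0309 with an SD of 0.36 over the genes, which argues against it. A compressed signal range or a floor would shrink differences until noise sets their sign. The 43 of those 99 genes above cortex in the adult thus cannot decide, and both stay open. The SD of log2 values on adult over P7 arrays, 0.972, was tried first and decides nothing, since RMA makes distributions alike. Without both adult replicate 1 arrays 1 gene was called again and the median of those 99 genes was -0.04, so the apartness of these arrays does not account for the pattern. The age of the animals and the myelination that goes with it were not tested here as causes.

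The second pattern is that transcripts of neurons were higher at P3 than at P7 in cortex samples that had been sorted for CD45 and CD11b. Carry-over of neuronal RNA or cells stays open, since the 12 of 14 neuron markers lower at P7, first set to count for it, restate the pattern. A difference between the P3 array set and the other set would move both regions alike, and the mean change of the regional difference over the neuron list was 0.18 with an SE over its members of 0.12, which leaves it open because the list means fell in both regions (-0.41 in cortex and -0.23 in corpus callosum). At P3, within a single array set, 12 of 14 markers were lower in corpus callosum than in cortex, with a list mean of -0.31. Age and array set coincide, and expression in the microglia themselves or uptake of neuronal material was not tested.

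The third pattern is that both adult replicate 1 arrays stood apart from adult replicates 2 and 3. A lower signal range on these arrays is a candidate explanation, since the SDs of their log2 values, 1.81 and 1.78, lay below the lowest of the other 16 arrays, 1.82, a margin that RMA may have narrowed. The sex of the animals may contribute, as both arrays were high in Xist, but the deviation of adult cortex replicate 1 from its group correlated with that of the likewise Xist-high P7 cortex replicate 1 with r = 0.21 across genes. With the Xist-high replicate 1 of corpus callosum P3, cortex P3 and corpus callosum P7 it gave 0.141, 0.0740 and 0.0989 (other P3 replicates were Xist-high too). Adult corpus callosum gave 0.147, 0.0390, 0.0538 and 0.0820 in the same order from cortex P7 on. All lay below the 0.5 set for sex and some below the 0.1 set against it, so sex stays open. Sample quality and the day of preparation were not given here and stay open.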

How the results depend on the processing

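The omission of both adult replicate 1 arrays and the 2 covariates were chosen after the result was seen, and the others were planned. Of the named genes, 3 of 26 called between the regions at P3 passed under every alternative, 11 of 23 at P7, 1 of 1 in the adult, 44 of 73 and 53 of 80 for adult against P7 in cortex and corpus callosum, 0 of 24 and 0 of 22 for P7 against P3, and 3 of 15 and 0 of 17 for the regional difference between P7 and adult and between P3 and adult. Leaving out an array reversed 0 of these called genes. Camera with an estimated correlation ended 74 of 87 called list results, and fry ended 37. Transcripts with a signal near the array background cannot be judged. A minimum difference of 1 by construction ended 29 and 26 calls for adult against P7. The neuron covariate ended all 24 for P7 against P3 in cortex. Other causes of moved values, beyond smaller sets and stricter rules, were not tested.

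Between the regions at P3 (112 genes) the count was 273 without dim probe sets, 197 with trend and robust estimation, 16 with only the compared groups, 61 with array weights, 42 at an absolute log2 difference of at least 1 and 14 with the neuron covariate. At P7 (100) it was 40 with only the compared groups, 236 with array weights and 51 at a difference of at least 1, and in the adult (1) 2 with only the compared groups, 3 with array weights and 2 with all probe sets. Adult against P7 in cortex (2264) gave 3861 with array weights and 578 at a difference of at least 1, and in corpus callosum (3822) 873 at a difference of at least 1. P7 against P3 in cortex (196) gave 644 with array weights and 77 at a difference of at least 1. In corpus callosum (164) it gave 301 without dim probe sets, 280 with trend and robust estimation, 5 with only the compared groups, 370 with array weights, 48 at a difference of at least 1 and 69 with the neuron covariate. The regional difference between P7 and adult (45) gave 87 without dim probe sets, 23 with renewed quantile normalization, 77 with trend and robust estimation, 24 with only the compared groups, 105 with array weights and 10 without both adult replicate 1 arrays. Between P3 and adult (40) it gave 202, 13, 96 and 4 under the first 4 of these, 80 with median centring, 0 without both adult replicate 1 arrays and 4 with the neuron covariate. The correlation of regional differences at P3 and P7 was 0.51 without dim probe sets.

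Without single arrays the counts ran from 29 to 126 at P3, 48 to 90 at P7, 1 to 3 in the adult, 1567 to 2117 and 2917 to 3541 for adult against P7 in cortex and corpus callosum, and 72 to 198 and 13 to 506 for P7 against P3. For the regional difference they ran from 0 to 1 between P3 and P7, 12 to 47 between P7 and adult and 0 to 101 between P3 and adult. The correlations of regional differences ran from 0.29 to 0.35 for P3 with P7, -0.16 to -0.08 for P3 with adult and 0.01 to 0.06 for P7 with adult.

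With the neuron covariate these list medians turned: immediate early (-0.21) and oligodendrocyte precursor (0.21) between the regions at P3; complement (-0.23), purinergic (-0.0407), oligodendrocyte precursor (0.0334) and border-associated macrophage (-0.18) for P7 against P3 in cortex; complement (-0.17) for the same ages in corpus callosum; and astrocyte (-0.34) for the regional difference between P3 and adult. Without dim probe sets the matrix list turned for P7 against P3 in cortex (0.23). Replicate numbers may mark pairs, which the main fit ignored. Same-number deviations correlated with r of 0.016 to 0.109 at P3, 0.0489 to 0.131 at P7 and 0.0615 to 0.300 in the adult. Of 6 arrays, 4, 6 and 5 correlated best with their own number. With the number as a block the regional difference gave 28 genes between P7 and adult and 21 between P3 and adult. No other count moved by more than 1.5 times. Between the regions the block kept 82 of 112 genes at P3 and 74 of 100 at P7. It ended 25 of 281 called gene and 0 of 87 list results.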

Other observations

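In this part the lists of acidification and hypoxia genes were chosen after the P7 differences were seen, and the outcome that would count for or against each was set before the list was tested. Of the gene families looked at after the data were seen, the histone genes are described.

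Histone genes, many of which are transcribed while DNA is copied, were looked at as a family without a test of enrichment. Of 29 measured genes 11 were lower in the adult than at P7 in cortex and 13 in corpus callosum, where H4c1 was higher (1.22). Called either way were 37.9% and 48.3% of the family, against 10.9% and 18.1% of other genes, with family medians of -0.55 and -0.62. H2bc12 gave -3.90 and -3.58, H1f1 -3.13 and -3.54, and H2ac15 -2.91 and -4.04. Renewed quantile normalization gave 12 and 13 lower, median centring 11 and 13. From P3 to P7 the family medians were 0.55 in cortex and 0.75 in corpus callosum, with 1 and 3 genes higher.

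Atp6v0d2, Gpnmb, Mitf and Rragd are genes of lysosome formation, and their higher levels in corpus callosum at P7 led to the hypothesis that the acidification machinery rises as a group. Of 24 genes of the vacuolar proton pump and its assembly, without those 4, 22 were measured, 21 of them higher in corpus callosum at P7, with a median of 0.25 (camera p 2.94e-12, 0.00733 with an estimated correlation) and 2 called singly. At P3 the median was 0.31 (0.0107 with an estimated correlation) and in the adult -0.15 (0.114). The list rose modestly at P3 and P7, and neither protein nor lysosomal pH was measured.

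Bnip3 and the glycolytic genes respond to low oxygen, and their rise led to the hypothesis of a hypoxia response in corpus callosum at P7. Of 18 hypoxia genes, without those named, 16 were measured, 15 of them higher at P7, with a median of 0.26 (camera p 2.97e-07, 0.0431 with an estimated correlation), although limma called 0 of them singly. At P3 the median was 0.48 but did not pass with an estimated correlation (0.0855), and in the adult it was -0.04 (0.671). Passing narrowly at P7 leaves the hypothesis open, and a change of metabolism without low oxygen could give the same values.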
